A study of Homo sapiens with 9 samples.

How the data were processed

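Total RNA from ALL-SIL, a T-cell acute lymphoblastic leukaemia line, was sequenced after electroporation with a non-targeting scrambled siRNA or with 1 of 2 siRNAs against TLX1, named s46 and s47 in the labels. Each of the 3 groups had 3 libraries, for 9 libraries in all, taken at 24 h. The labels give a dose of 400 nM for the scrambled siRNA. No label says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Ribosomal RNA was depleted and the libraries were stranded, per the labels' protocols.

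The authors deposited raw read counts per gene, 1 file per library, made against GRCh38 per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here. Each deposited file holds 3 count columns, for reads counted without regard to strand and for each strand. The sense column held most gene reads and was used for the tests; the opposite-strand column held 5.22% to 6.32% of the stranded gene reads. The first 4 lines of each file name no gene and were left out of library sizes and tests. Unmapped reads were 4.52% to 6.70% of all reads, multimapping reads 6.36% to 14.5%, reads outside annotated genes 23.8% to 36.8% and ambiguous reads 2.12% to 4.45%. Multimapping and ambiguous reads are listed apart from the genes in the deposited files, so genes with near-identical copies can be undercounted.

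The files list 58096 gene IDs, of which 57492 matched GENCODE 29 by ID and 604 did not. Symbols, gene types, coordinates and 3′ UTR sequences were taken from that annotation on GRCh38. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 16072 genes, 2845 of them long non-coding. Counts were scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3, in 1 fit of all 9 libraries with the group as the only term. Contrasts were the mean of both TLX1 siRNAs against scrambled, each siRNA against scrambled, and s46 against s47. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistics, and CPM values are TMM-scaled.

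In total, 26 gene lists were fixed, and the 23 with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. The correlation was also estimated from the data, and fry was run. The groups, contrasts, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes TLX1; the 12 largest changes each way among genes past the threshold in the same direction with both siRNAs at log2 CPM of at least 1; up to 5 long non-coding RNAs each way; up to 5 genes each way for s46 against s47; and up to 4 called members per list. Members of a list that were not called are named with values only. A gene that the rule takes is not reported here.

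Depth was 21134650 to 33393740 sense gene reads per library. On counts simulated from the real means, dispersions and library sizes, with 15711 genes tested, the mean of both siRNAs recovered 59 of 100 genes changed 2-fold and 24 of 100 changed 1.5-fold, with 6 false calls. The gene-list test was tested on simulated data with a single list raised 1.5-fold. That list was called (camera adjusted p 8.69e-21) and no other list was. Genes were drawn independently there, so this cannot show how often camera calls lists of correlated genes by chance.

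Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, unstranded counts, fits of only the groups compared, the replicate number as a block, a fold minimum of 1.2, and leaving out each library. No gene held over 1% of any library, so the alternative that leaves out such genes removed nothing and was not run. Every 7-base word in 3′ UTRs was tested for association with the signed test statistic over 9766 protein-coding genes, given UTR length, base composition and expression. The word test used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.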

Results

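RNA from 9 ALL-SIL libraries was counted per gene, 3 each for a scrambled siRNA, siRNA s46 and siRNA s47, the last 2 directed against TLX1. TLX1 is a homeobox transcription factor that drives a subset of T-cell acute lymphoblastic leukaemia. Sense gene reads ranged from 21134650 (scrambled replicate 1) to 33393740 (s46 replicate 3). Replicates within a group correlated at r = 0.985 to 0.990 across genes for the siRNA groups. Scrambled replicates 2 and 3 correlated at 0.989, but replicate 1 correlated with them at 0.9672 and 0.9752. Scrambled replicate 1 also had 14.5% multimapping reads against 6.36% to 7.34% in the other 8 libraries, and 39.9% of its reads fell in genes. The share of stranded gene reads on the opposite strand was 5.37% ± 0.134 (SD, n = 6) in the TLX1 siRNA libraries and 5.87% ± 0.433 (SD, n = 3) in the scrambled ones (exact permutation test, two-sided p 0.0357 over 84 splits, adjusted p 0.25 over 7 measures of the reads). The adjusted p of the other 6 measures was 0.25 to 0.607, and scrambled replicate 2, at 5.46%, lay within the range of the siRNA libraries.

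The targeted gene was examined first. TLX1 (ENSG00000107807.12, chromosome 10, 101130505 to 101137789, GRCh38) fell with both siRNAs. Its level was 185.9 CPM ± 13.5 (SD, n = 3) with scrambled siRNA, 76.6 ± 11.9 (SD, n = 3) with s46 and 70.8 ± 6.28 (SD, n = 3) with s47. Every siRNA library, at 63.5 to 87.3 CPM, lay below every scrambled library, at 171.3 to 198.1 CPM. The log2 fold change for the mean of both siRNAs was -1.34 ± 0.11 (SE; edgeR adjusted p 0.000394), a 2.52-fold reduction. It was -1.28 with s46 and -1.39 with s47, and the difference between the siRNAs did not pass the test (log2 difference 0.11 ± 0.13 SE, edgeR adjusted p 1).

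**Figure D1:**
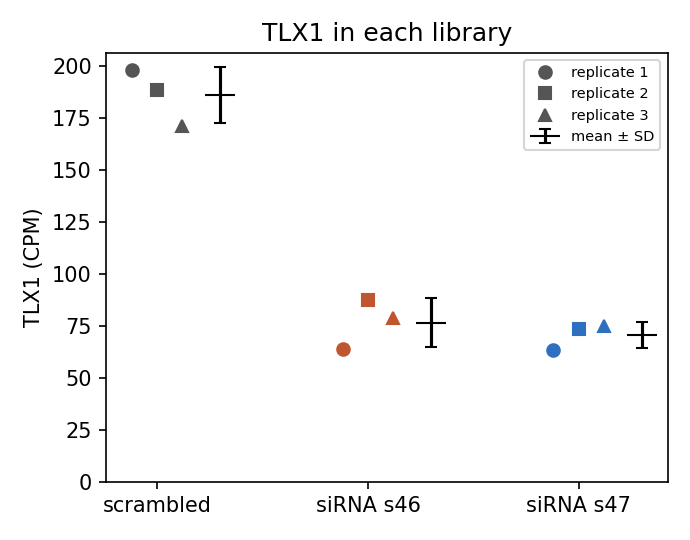
TLX1 level in CPM (y axis) in each library of the 3 siRNA groups (x axis); symbols mark replicates and bars the mean ± SD. All 6 TLX1 siRNA libraries lie at or below 87.3 CPM and all 3 scrambled libraries at or above 171.3 CPM.

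The comparison of both siRNAs with scrambled siRNA asks which transcripts differ when TLX1 is reduced. Both siRNAs were set against the same scrambled libraries, so an effect of the scrambled siRNA itself would also appear as a change with both. The largest rises shared by both siRNAs were in TC2N (chromosome 14, 91779751 to 91867536; log2 fold change 2.67 ± 0.26 SE), DAB2IP, a Ras GTPase-activating protein (2.21 ± 0.32), TSHR, the thyrotropin receptor (1.68 ± 0.17), and IL7R, a cytokine receptor of developing T cells (1.54 ± 0.16). TOP1MT, the mitochondrial topoisomerase I (1.28), SCAMP1 (1.01), the RNA-binding protein LSM14A (0.93), the nuclear pore membrane protein NDC1 (0.90) and the kinase HIPK3 (0.86) also rose. The T-cell receptor segment TRBV7-2 rose by 1.30, an uncertain value because reads can be split among similar segments. RXRA, a nuclear receptor (chromosome 9, 134317098 to 134440585; -1.43 ± 0.16), the chemokine receptor gene CCR4 (-1.27 ± 0.13) and the cytokine receptor gene IL9R (-0.94 ± 0.13) fell. The edgeR adjusted p of these genes was 0.000842 (TC2N, TSHR, IL7R and CCR4) to 0.0155 (TRBV7-2). TC2N and DAB2IP were low with scrambled siRNA, at means of 0.60 and 1.4 CPM, so their fold changes start from low levels.

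In total, 91 of 16072 genes passed the threshold for the mean of both siRNAs, 66 higher and 25 lower (edgeR, 3 libraries per group), and 2859 had an unadjusted p under 0.05. Of the 63 higher genes with an annotated 3′ UTR, 30 (47.6%) carried the word GCAGTAC in it, against 5.02% of the 10900 other genes (Fisher's exact test p 3.51e-22, two-sided). TC2N, SCAMP1, LSM14A, NDC1 and HIPK3 carried it, and DAB2IP, TSHR, IL7R and TOP1MT did not. TSHR carried the overlapping word CAGTACA, and 34 of the 63 (54.0%) carried either word, against 11.6% of the other genes. Among the 23 lower genes with a 3′ UTR, 1 carried it. The word was chosen after its values were seen. The count was 1650 without scrambled replicate 2, of which 813 were higher and 837 lower, and 22 without scrambled replicate 3; it was 45, 60 and 44 without s46 replicates 1, 2 and 3, and 41, 60 and 42 without s47 replicates 1, 2 and 3. With library totals in place of TMM the calls were 49 higher and 30 lower, and with DESeq2 253 and 205; TOP1MT and TRBV7-2 lost their calls without scrambled replicate 3 (adjusted p 0.0669 for both).

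**Figure D2:**
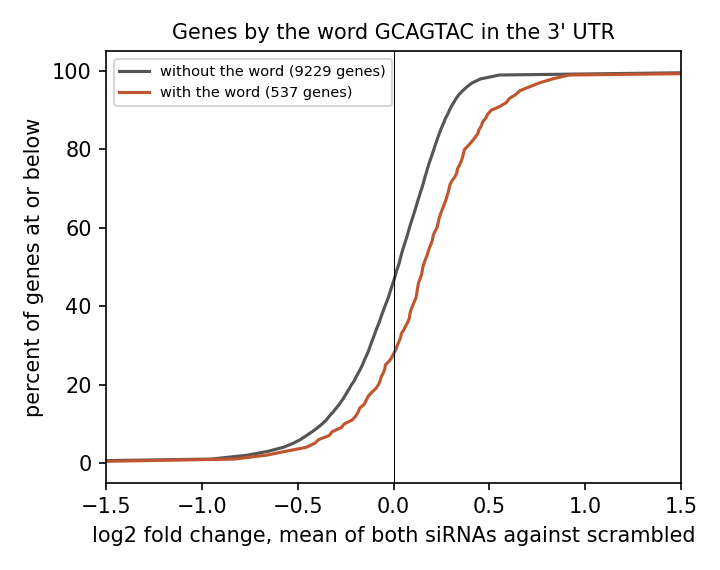
Cumulative percent of genes (y axis) by log2 fold change for the mean of both siRNAs against scrambled (x axis), for 537 protein-coding genes with the word GCAGTAC in the 3′ UTR and 9229 without it. The curve with the word lies to the right; the medians were 0.15 and 0.02.

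With s46 alone, 28 genes passed the threshold, 24 higher and 4 lower, and with s47 alone 53 did, 39 higher and 14 lower. Genes past the threshold in the same direction with both siRNAs numbered 25, of which 21 were higher and 4 lower; TLX1, RXRA, CCR4 and IL9R were the 4 lower ones. All 25 also passed for the mean of both siRNAs. Independent lists of these sizes would share 0.0582 higher and 0.00348 lower genes, and simulated unchanged groups with shared simulated controls shared at most 0. All 9 libraries were redrawn there from common means and spreads, so the real deviation of scrambled replicate 1 is absent. Of the 19 higher genes with a 3′ UTR, 13 (68.4%) carried GCAGTAC. The s46, s47 and shared counts were 225, 275 and 168 without scrambled replicate 2, 5, 5 and 4 without scrambled replicate 3, and 48, 69 and 43 without scrambled replicate 1; leaving out s46 replicates 1, 2 and 3 gave 4, 4 and 5 genes for s46, 24, 24 and 16 for s47 and 4, 4 and 5 shared, and leaving out s47 replicates 1, 2 and 3 gave 15, 17 and 6 for s46, 4, 6 and 8 for s47 and 4, 4 and 6 shared. Fitting only the groups compared gave 6, 8 and 6.

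With s46 and s47, the log2 fold changes were 2.40 and 2.94 for TC2N and -1.31 and -1.23 for CCR4. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.81 with a covariance of 0.1395. Unchanged groups simulated with shared simulated controls gave r = 0.51 and a covariance of 0.0551, a difference in covariance of 0.0843. The simulations lack the deviation of scrambled replicate 1 and any structure by replicate number. They may therefore understate what the real controls produce. Part of the excess may come from the shared controls, since 3 control libraries cannot be split into parts of at least 2.

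**Figure D3:**
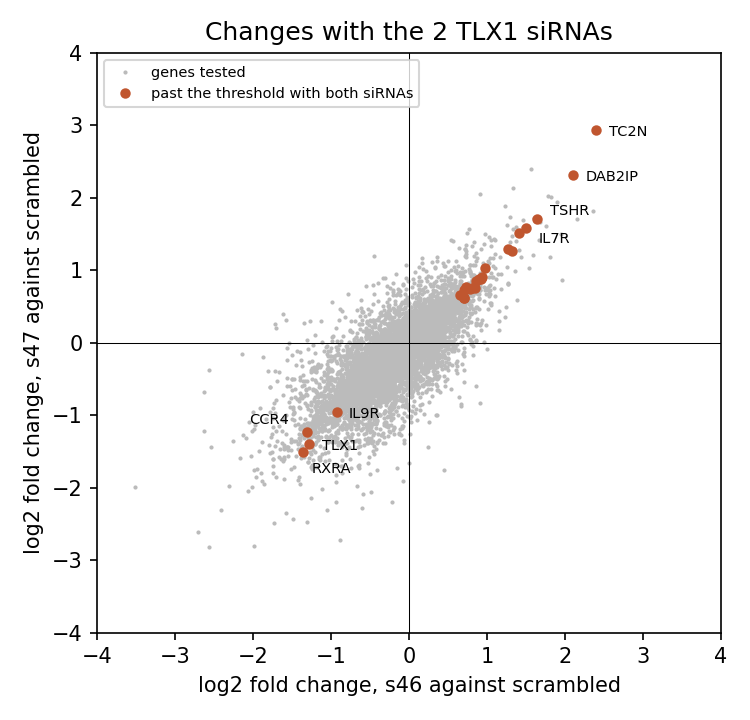
Log2 fold change against scrambled for siRNA s46 (x axis) and s47 (y axis), 1 point per gene tested; orange points are the 25 genes past the threshold in the same direction with both. TC2N lies highest at 2.40 and 2.94, and TLX1 lies at -1.28 and -1.39.

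In the direct comparison of s46 with s47, 0 genes passed the threshold by edgeR, 113 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. TLX1 itself differed by 0.11 ± 0.13 (SE). Across 9766 protein-coding genes with a 3′ UTR, the word AATCACT went with lower levels under s47 than under s46 (z 13.2 against at most 4.99 in 100 shuffles of genes); this word, too, was chosen after its values were seen.

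Long non-coding RNAs were tested because total RNA holds transcripts without poly(A) tails. Of 2845 tested, AC011893.1 (ENSG00000226806.1, chromosome 2, 135820191 to 135823087), which lies on the strand opposite LCT, was the 1 past the threshold with both siRNAs. It rose by 1.46 ± 0.19 (SE, edgeR adjusted p 0.00612). For the mean of both siRNAs 1 long non-coding RNA was higher and 2 were lower. The shared count was 6 without scrambled replicate 2, and 0 without scrambled replicate 3 and without each of the 6 TLX1 siRNA libraries.

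Genes of cortical thymocytes, the stage at which T-cell receptor genes rearrange, lay higher with the TLX1 siRNAs, with a median log2 fold change of 0.53 over 16 genes (camera adjusted p 3.61e-05). That call was lost with the correlation estimated in the main fit (adjusted p = 0.709 with an estimated correlation of 0.28). With the replicate number as a block, cortical thymocyte genes were the only list that passed with the correlation estimated (adjusted p = 0.043 with an estimated correlation of 0.019). That combination was chosen after the data were seen. In this list 2 genes rose and 0 fell, both over all genes and adjusted over the list alone: DNTT, the terminal transferase (1.44 ± 0.22 SE, edgeR adjusted p 0.0118), and ARPP21 (0.84 ± 0.13, 0.0135). Of the 16 log2 fold changes 12 were above 0 and 4 below; RAG2 (1.24 ± 0.47), RAG1 (1.17 ± 0.44), CD1A (0.87 ± 0.32) and PTCRA, the pre-T-cell receptor alpha chain and the lowest member (-1.15 ± 0.64), did not pass. RAG1 carries the word GCAGTAC. DNTT and ARPP21 lost their calls without scrambled replicate 3 (adjusted p 0.0669 for both), and 61 of 100 splits of the libraries gave at least as many lists as the 5 called.

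The other 4 lists called by camera were also higher. MYC and ribosome biogenesis genes had a median of 0.23 over 48 genes (camera adjusted p 1.51e-06), and ODC1, the first enzyme of polyamine synthesis, rose (0.73 ± 0.14 SE, edgeR adjusted p 0.0299), the 1 member called, also adjusted over the list alone. Cytosolic ribosomal protein genes had a median of 0.16 over 78 genes (6.14e-06), heat-shock genes 0.23 over 21 (0.000287) and G1/S and DNA replication genes 0.14 over 53 (0.00342). No member of these 3 lists was called over all genes; adjusted over the list alone, 2 heat-shock genes were higher and 0 in the other 2. ODC1 lost its call without scrambled replicate 3 (adjusted p 0.116), each s46 library (0.0716, 0.0724 and 0.0922 without replicates 1, 2 and 3) and s47 replicates 1 and 3 (0.0863 and 0.0956). All 4 calls were lost with the correlation estimated (adjusted p = 0.709, 0.746, 0.709 and 0.746 with an estimated correlation, in that order), and fry gave adjusted p of 0.254, 0.598, 0.239 and 0.644. Without scrambled replicate 1 the ribosomal protein median was 0.017 (camera adjusted p 0.534), the heat-shock median 0.10, the MYC median 0.14 and the G1/S median 0.18. The G1/S list lost its call without scrambled replicate 2, s46 replicate 1 or s47 replicate 1 (adjusted p up to 0.444).

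**Figure D4:**
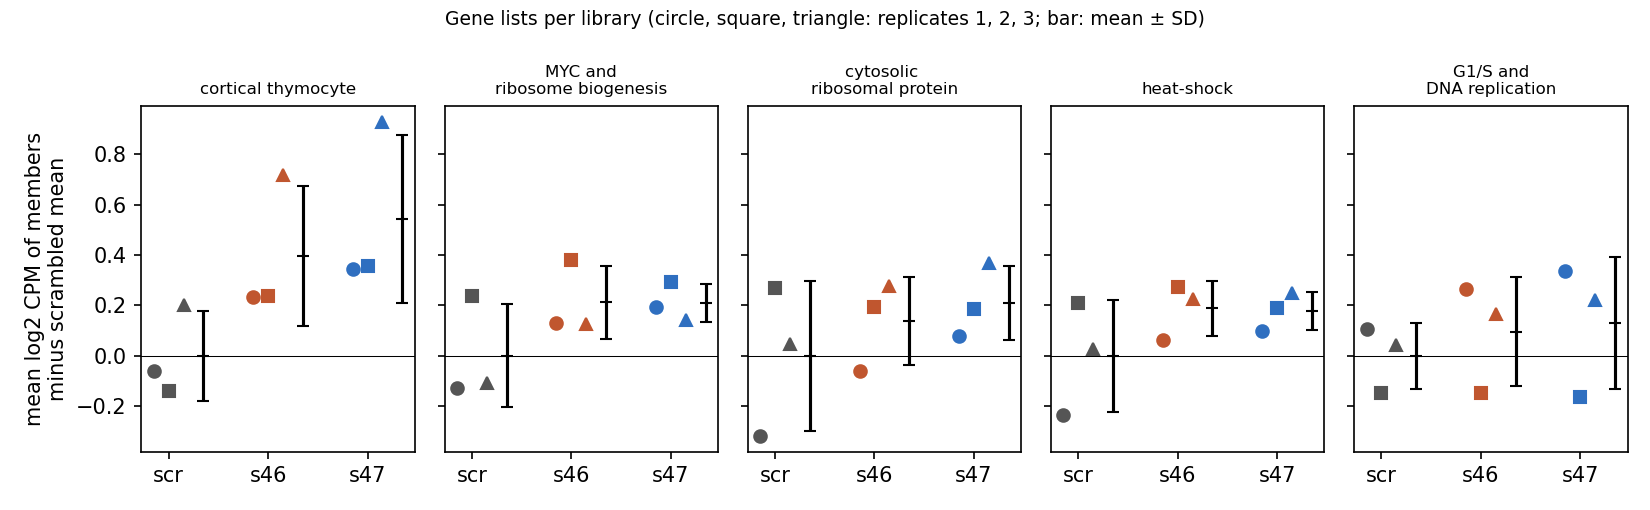
Mean log2 CPM of each list's members minus the scrambled mean (y axis) per library for scrambled (scr), s46 and s47 (x axis), 1 panel per list called by camera; symbols mark replicates and bars the mean ± SD. Scrambled replicate 1 lies lowest in the ribosomal protein panel, and replicate 3 lies highest within each siRNA group in the cortical thymocyte panel.

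No other list passed; the lowest camera adjusted p of the other 18 was 0.0945. G2/M and mitotic checkpoint genes, with a median of -0.03, passed at -0.17 without scrambled replicate 1 and at 0.19 without scrambled replicate 2. Glycolysis and hypoxia genes passed without scrambled replicate 1 (-0.09), and JAK-STAT targets without the 3 libraries of number 1 (0.04). In the 3 lists with fewer than 5 tested genes (early progenitor, myeloid, and erythroid and megakaryocyte genes) the edgeR adjusted p of single genes was 0.184 (TFRC, 0.50) to 0.967 (ITGAM, -0.06). Mature T-cell and thymic egress genes went both ways: IL7R rose while CCR4, the homing integrin ITGB7 (-1.18 ± 0.20 SE, edgeR adjusted p 0.0201) and the chemokine receptor CXCR3 (-1.78 ± 0.28, 0.0135) fell, over 21 genes with a median of -0.09. Adjusted over the list alone, 4 were higher and 3 lower. ITGB7 lost its call without scrambled replicate 3 (adjusted p 0.111), s46 replicates 2 and 3 (0.0556 and 0.0621) and s47 replicates 1, 2 and 3 (0.0513, 0.0553 and 0.0607), and CXCR3 without the 3 libraries of number 1 (0.0668). NK and cytotoxic markers had a median of -0.38 over 8 genes with 0 called (camera adjusted p 0.0945). That list passed without scrambled replicate 1 (median -0.51, adjusted p 0.00379) and without the 3 libraries of number 1 (-0.31, 0.0129), and its median was -0.12 without scrambled replicate 3 and -0.21 without s46 replicate 2. Among 5 B-cell markers, IGLL1, the surrogate light chain, rose (1.52 ± 0.23, edgeR adjusted p 0.012), and lost its call without scrambled replicate 3 (0.083). SHQ1 of the NOTCH list rose (0.61), while PRKCQ of the T-cell receptor list (-0.60) and SLC7A11 of the stress response list (-0.57) fell; each lost its call without scrambled replicate 3 (adjusted p 0.159 for SHQ1, 0.131 for PRKCQ and 0.131 for SLC7A11). SHQ1 also lost it without s46 replicates 1, 2 and 3 (0.107, 0.0724 and 0.0974) and s47 replicates 1, 2 and 3 (0.107, 0.0596 and 0.107), PRKCQ without the same libraries (0.0983, 0.0704 and 0.0665; 0.0577, 0.0613 and 0.0765), and SLC7A11 without s46 replicates 1 and 3 (0.0848 and 0.0961) and s47 replicates 1, 2 and 3 (0.0875, 0.0618 and 0.0801).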

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

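The tests of words in the comparison of s46 with s47, the tests of the ribosomal protein, MYC and G1/S lists taken singly, the test of the word in the cortical list, how the intervals of the cortical list were read, and the label check of scrambled replicate 1 were chosen after the result was seen. Of the word tests, that for the mean of both siRNAs was written down first.

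In the difference between the siRNAs, the word AATCACT went with higher values under s46 than under s47 (z 13.2, at most 4.99 in 100 shuffles), and the word AACCGCA with lower ones (z -5.82, at least -5.01 in the shuffles), although no single gene passed the test. AATCACT had z of -8.79 and -4.38 in s47 replicates 2 and 3 but 1.10 in s47 replicate 1, each against the other groups.

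Counts on the strand opposite the annotated genes gave 2 genes past the threshold for the mean of both siRNAs, of 9964 tested. They were LCT (1.56 ± 0.23 SE, edgeR adjusted p 0.016) and AP000345.1 (1.75 ± 0.25, 0.0142). They lie opposite AC011893.1 (1.46) and IGLL1 (1.52), both of which rose in sense counts. Where they overlap, a sense read of AC011893.1 or IGLL1 also counts on the strand opposite LCT or AP000345.1. The 2 calls may therefore hold the same reads.

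More genes were higher than lower with both TLX1 siRNAs (72.5% of calls), but not without scrambled replicate 2 (49.3%) or with no filter on low counts (37.1%). A candidate explanation is that the scrambled siRNA lowers transcripts matching its own seed, which would leave them higher in every other library. Among 15611 words, GCAGTAC went most with higher values (z 16.2, at most 5.37 in the shuffles), came first on odd and on even chromosomes (z 12.7 and 10.2), and had z of -7.33, -13.6 and -11.8 in scrambled replicates 1, 2 and 3. The scrambled sequence is not used here, so a match to it was not tested; leaving out the carriers of a word picked for higher values must lower the higher calls (28 higher and 17 lower; of shared genes 3 and 3, where genes without the word lost their calls too), so that count decides nothing. Scaling stays open: with library totals 62.0% of calls were higher (95% Wilson interval 51.0% to 71.9%). A change that follows TLX1 itself was not excluded, either for genes with the word or for those without it, such as IL7R and DAB2IP.

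For the gene lists, camera's preset correlation may be too low, and at least 5 lists were called in 61 of 100 splits, with up to 7, so chance cannot be excluded for their number. For cortical thymocyte genes the median was 0.52 without scrambled replicate 1 (99.9% of its value, 95% bootstrap interval 53.3% to 191%, camera adjusted p 1.78e-06). It was 0.44 after trends of GC content, length and expression were removed (83.4%, 62.1% to 137%, camera adjusted p 0.00155). Of the list's 16 members 1, RAG1, carries GCAGTAC or the overlapping CAGTACA (6.25%, exact 95% interval 0.158% to 30.2%), too few to move a median. That argues against matches to these words in the members themselves as the whole cause. An indirect effect of the scrambled siRNA on these genes was not tested. The bootstrap resampled the member genes, not the libraries, so its intervals leave out the spread between libraries. In the first 2 tests, camera passed with its preset correlation and both intervals lie above the share written down for a cause. Within these libraries, that argues against each as the whole cause. Both intervals reach below the share written down for no cause, and by that stricter reading both causes would stay open. For the other 4 lists together the medians were 0.085 and 0.027 in these 2 tests, which leaves both open: ribosomal protein genes had 0.017 and -0.0057, as either cause would need, MYC genes kept 0.14 and 0.12 (59.8% and 54.9%, camera passing), between the shares written down for a cause and for none, and G1/S genes kept 0.18 without scrambled replicate 1, which argues against it for them, but had 0.0091 after the trends were removed. Heat-shock genes kept 0.10 without scrambled replicate 1 (43.9%, camera adjusted p 0.0208). After the trends were removed they kept 0.087 (38.1%, camera adjusted p 0.0536), so both causes stay open for them. A response to TLX1 remains untested apart from these causes.

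Scrambled replicate 1 stood apart from the other libraries. Thinned to 21134650 gene reads each, scrambled replicates 2 and 3 still correlated at 0.989 against 0.968 and 0.976 for pairs with replicate 1, which argues against depth. GC content and length explained 8.24% of the variance of its deviation, under the 10% set beforehand, and its TLX1 level of 198.1 CPM lay above all siRNA libraries (at most 87.3), which argues against a wrong label. What sets it apart may lie in the sample or its preparation, which was not tested.

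Other splits of the libraries were fitted for each count. For the mean of both siRNAs (91 genes), 3 of 100 splits, the real one included, gave as many, under the 5% set beforehand. That argues against chance only as far as the libraries are interchangeable. The highest other, 134, took the 3 libraries of number 1 as controls. A structure of the samples by number may underlie it (222 genes with the replicate block). The check used for pairing by number was not met, and the splits made no allowance for such a structure. Another split, with 133, kept the scrambled controls and mixed the siRNAs. For genes shared by both siRNAs (25) 4 of 100 gave as many (highest other 58), also under the 5% set beforehand and with the same limit. For shared long non-coding RNAs (1) 4 of 100 did (highest other 4), under the 5% set beforehand. That share rests on 1 gene, which lost its call without scrambled replicate 3 or any 1 TLX1 siRNA library, so chance stays open for it. For s46 (28 genes), s47 (53) and their difference (0), 10 splits are too few for a share under 0.05; the highest other was 0 in each, with 1, 1 and 10 splits as large.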

How the results depend on the processing

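TLX1 fell under all 12 alternatives and in all 9 fits that left out a library (log2 fold change -1.40 to -1.18, leave-one-out -1.39 to -1.27). In the tally that follows, lists were tested by camera at its preset correlation. In the main fit, every list call was lost with that correlation estimated and with fry. Under other settings, 277 and 224 tests of single named genes and lists kept their side of the threshold. There 17 and 0 lost it, and 0 and 5 gained it. In fits that left out a library 188 and 199 kept it, 37 and 4 lost it and 0 and 3 gained it. In those fits 0 and 1 passed in the other direction. The last was the list of G2/M and mitotic checkpoint genes (median 0.19 without scrambled replicate 2, -0.17 without scrambled replicate 1); the cause was not tested.

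Counts below are for the mean of both siRNAs, s46, s47, genes shared by both, and shared long non-coding RNAs, in that order (91, 28, 53, 25 and 1 as reported). DESeq2 gave 458, 196, 203, 141 and 7. With no filter on low counts they were 876, 384, 432, 269 and 23, the difference between siRNAs gave 3 genes, 325 were higher and 551 lower, and the correlation of the siRNAs was 0.57 over 31261 genes. At 1 CPM in 3 libraries that correlation was 0.90. A fold minimum of 1.2, which asks for larger changes, gave 23, 5, 13, 5 and 0. With library totals s46 gave 14 and the shared genes 14. With only the groups compared, and so fewer libraries behind each spread, s46, s47 and shared counts were 6, 8 and 6, with 0 long non-coding RNAs. The number of lists, 5, was 0 with the correlation estimated and 0 with fry. Leaving out 1 library gave ranges of 22 to 1650, 4 to 225, 4 to 275, 4 to 168 and 0 to 6, with 4 to 7 lists and correlations of 0.68 to 0.86. Apart from fewer genes, libraries or a larger fold asked for, the cause was not tested.

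The check used for pairing by number was not met: 8 of 9 same-number pairs had correlated deviations above 0.1 and the lowest was -0.03. Even so, all 9 libraries correlated best with their own number. Same-number correlations reached 0.436, while those between other numbers were -0.31 to 0.17. Such structure by number is left out of the main fit, and the labels do not say what the numbers share. With the replicate block the counts were 222, 74, 125, 65 and 2.

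The following alternatives were chosen after seeing the data. The replicate block without scrambled replicate 1 gave 506, 320, 426, 270 and 8, with 6 genes for the difference, 8 lists and a correlation of 0.72. The block with the correlation estimated gave 1 list, cortical thymocyte genes (adjusted p = 0.043 with an estimated correlation), and fry with the block 3: cortical thymocyte and T-cell receptor genes (adjusted p 0.00198 for both) and NK and cytotoxic markers (0.0153). With the block, the median log2 fold change was 0.52 for cortical thymocyte genes, -0.11 for T-cell receptor genes and -0.36 for NK and cytotoxic markers. Without the 3 libraries of number 1, s47 gave 33 genes and the correlation was 0.64. Without the genes that carry GCAGTAC the first 4 counts were 45, 6, 23 and 6. Small changes were often missed: for the mean of both siRNAs, 24 of 100 simulated 1.5-fold changes were found. Whether depth, spread or the number of libraries sets this was not tested.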

Other observations

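Transcripts encoded in the mitochondrial genome were examined after the data were seen. Over 23 such genes the median log2 fold change for the mean of both siRNAs was -0.54 (range -2.69 to 0.57), and none passed the edgeR test over all genes. Gene types were not taken apart, and scrambled replicate 1, whose read shares stood apart, was included.

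Each TLX1 siRNA may also lower transcripts that match its own seed, a hypothesis formed after the values were seen. The word AATCACT, lower under s47 than under s46, had z 13.2 in the difference. It came first on even and on odd chromosomes (9.44 and 9.14), with the overlapping word ATCACTA second (10.6). The word AACCGCA, lower under s46 than under s47, had z -5.82 and came first on even chromosomes but at rank 3 on odd ones. Against scrambled siRNA, AATCACT was not among the 12 lowest words with s47, nor AACCGCA among the 12 lowest with s46. Both tests of the difference could have come out below the shuffles. The shuffles are a low bar: for the mean of both siRNAs the word GGGGGAG had z -6.61, against at least -5.13 in the shuffles. Passing them at z -5.82 therefore does not single out a seed match for AACCGCA. The siRNA sequences are not used here, so the match itself was not tested.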
